A study of Homo sapiens with 18 samples.

How the data were processed

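The series measured total RNA from BEAS-2B, an immortalised human bronchial epithelial cell line, on 18 Illumina bead arrays in 6 groups of 3. Per the labels, cells received for 4 h or 24 h an organic extract of particulate matter (PM) from the exhaust of a gasoline engine. The engine ran either on neat gasoline (E0) or on gasoline with 15% ethanol by volume (E15), and the extract was given at 50 µg PM per ml. Control cells received an extract of an unexposed filter (blank) for the same times. Per the labels, the replicates of a group were wells seeded from independent cell populations, so p-values here measure the spread between such wells.

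The table of probe intensity values was deposited on a linear scale with neither background subtraction nor normalization, per the file headers and the range of the values, whose lowest value per array lay between 65.4 and 85.1. The same deposited table gives a detection p-value for each probe on each array, per the file headers. Column headers for the detection p-values of 2 arrays repeated another name, and their place beside the intensities was checked. The weakest Spearman rho between detection p-value and intensity within an array was -0.986, and the strongest with any other array had a size of 0.854. The authors also deposited processed log2 values, in which the sorted values of all 18 columns differed by at most 5e-09, as quantile normalization gives. Each processed column ranked the probes as the intensities of its own array did (lowest Spearman rho 0.999973, highest with another array 0.863). The median of every processed column was 6.67. GenomeStudio 2 and lumi are the tools named in the submitters' processing notes, and their settings are not given in the sources used here. No sample column of the tables was left unused (0 columns).

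The intensities were background corrected by normexp with an offset of 16, estimated from the detection p-values, then quantile normalized between arrays and taken to log2, with the neqc function of limma 3.58.1 in R 4.3.3. Of 47323 probes, 30113 carried 1 gene symbol in the platform annotation, 8 carried several genes and 17202 carried none. Of the named probes, 30074 were found in the RefSeq gene table, and 0 symbols were updated. A probe was kept where its detection p was below 0.05 in all 3 arrays of at least 1 group, which left 17388 probes, 13455 of them with 1 gene. Each gene was represented by its kept probe with the highest mean level, giving 10383 genes, of which 2529 had more than 1 kept probe. A probe with several genes named none, and 3933 kept probes without a gene name were tested only as probes.

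One limma model with a mean per group was fitted to all 18 arrays, so that the 6 groups shared 1 estimate of the spread per gene with 12 residual degrees of freedom. The comparisons were each extract against the blank of its time, E15 against E0 at each time, the blank at 24 h against 4 h, and the differences of the responses between times (interaction contrasts). Genes with a Benjamini-Hochberg adjusted p below 0.05 over 10383 genes were called, and the adjusted p-values of single genes in all parts come from this limma model. Errors of log2 fold changes are the model's standard errors (SE), with a median of 0.265 for comparisons of 2 groups and 0.375 for interactions. Where all arrays of one group had a probe not above background, the fold is given as "at least", against the lowest signal above background on those arrays.

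Lists of genes were fixed with the rest of the design, and 21 were written: aryl hydrocarbon receptor targets, NRF2 antioxidant genes, xenobiotic phase I and II enzymes, cytokines and NF-kB response, p53 and DNA damage response, integrated stress and unfolded protein response, heat shock proteins, immediate early and MAPK feedback genes, mitotic genes, DNA replication genes, cholesterol synthesis, PPAR and lipid droplet genes, metallothioneins and metal response, hypoxia response, TGF-beta and extracellular matrix, interferon response, reference genes, and markers of airway ciliated and secretory cells, squamous and basal keratinocytes, fibroblasts and immune cells. The airway list had 0 of 16 members past the detection filter, so 20 lists were tested in 6 comparisons with limma's camera. The preset inter-gene correlation was 0.01, and p-values were adjusted over the 120 tests. The same tests were run with a correlation estimated from the residuals, and their adjusted p is printed beside the lists as the adjusted p with an estimated correlation. A count of list members "adjusted over the list alone" uses a Benjamini-Hochberg adjustment within the list.

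The grouping, the tests, the gene lists, the processing alternatives and the rule for the genes named were chosen before the data were examined. For each comparison against the blank and of E15 against E0, the rule names the 10 largest rises and the 10 largest falls among called genes whose 3 arrays of one group all lay beyond the 3 of the other. It adds CYP1A1, CYP1B1, TIPARP, AHRR, ALDH3A1, NQO1, HMOX1, GCLM, SLC7A11, IL6, CXCL8, IL1B, PTGS2, CDKN1A, GDF15, DDIT3, ATF3 and MKI67, called or not, and up to 4 members with the smallest adjusted p from each list holding a called gene. For the interactions it takes the 5 largest called values each way. List members printed for other lists, and the genes of the blank comparison, were chosen after their values were seen.

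On simulated arrays for E15 against blank at 24 h, with 10383 genes and 10 runs, the model recovered 47.5% of genes seeded with a 2-fold change and 91.8% of those with a 4-fold change, with a mean of 6 false calls, when the noise was independent between arrays. With noise that shared 1 component across arrays, taken from the residuals of these data, it recovered 38.4% and 91.7%, with a mean of 1.4 false calls. Residuals cancel within each group, so this component could widen the errors but not move a group mean. The 1.4 false calls thus do not give the rate for a component that falls unevenly on the groups. The list test was simulated with independent noise only, at an unadjusted p below 0.05 for each list. It called 10 of 10 lists of 13 genes shifted by -0.5 on the log2 scale and 1 of 10 lists not shifted. False list calls under the shared component were not simulated, but list tests were run on other splits of the arrays with the real group means removed. Of 99 such splits, 72 had any list call with the preset correlation (median 4, highest 29). With an estimated correlation 1 of 99 had any, so the adjusted p-values with the preset correlation were too small for these arrays.

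Between 17213 and 19096 probes per array (36.4% to 40.4%) had a detection p below 0.05, and the median intensity of probes at background lay between 85.4 and 104 per array. The number of arrays limits the precision. No pair of columns held identical values (0 pairs). The alternatives tried were no background correction, a normexp offset of 50, median scaling, cyclic loess, the authors' processed values, no detection filter, a detection p below 0.01 in all 18 arrays, the mean of a gene's probes, every probe on its own, only the groups compared, the replicate number as a block, a trended robust variance, array weights, an added 2-fold threshold, an estimated correlation in the list tests, and leaving out each array. Chosen after seeing the data were a covariate for the first residual component, a covariate for the array background level, leaving out 5 arrays with high scores on the first principal component, and list tests of the blank comparison and of the interactions. A block for the chip was not run, since the files used here name no chip.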

Results

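Transcript levels were measured in BEAS-2B cells, a human bronchial epithelial line, after exposure to organic extracts of engine exhaust particles. The extracts came from combustion of neat gasoline (E0) or of gasoline with 15% ethanol (E15) and were given at 50 µg PM per ml for 4 h or 24 h. Each of the 4 exposed groups and both blank groups held 3 arrays, and 17213 to 19096 of 47323 probes were detected per array. Pairs of arrays within a group correlated at 0.931 to 0.980 across the 10383 genes tested (18 pairs, median 0.965), and pairs from different groups at 0.915 to 0.987 (135 pairs). Genes are not independent replicates in such correlations. A single component held 42.3% of the variance within groups, and the arrays' scores on it rose with the deviation of their background level from its group mean (Pearson r = 0.746, Spearman rho = 0.695, 18 arrays). Permutation of all arrays gave a permutation p = 0.00039 and 0.00209 (adjusted 0.00078 and 0.00418 over 2 relations). A test within groups, added after this result was seen, gave a permutation p = 0.00409 and 0.0104 (adjusted 0.00818 and 0.0302 over 4 relations). Without the 2 arrays of largest deviation, r was 0.656. The background level itself, also added later, gave r = 0.727 and rho = 0.655 (permutation p within groups 0.00409 and 0.0151). The deviation of mean array intensity had r = 0.355 (permutation p = 0.149) and rho = 0.36 (permutation p = 0.141). Against random lists of the same size and similar mean level, the cholesterol synthesis list had a mean weight on this component at percentile 3.55. Heat shock proteins lay at 3.15, immune cell markers at 4.35, cytokines at 94.4 and PPAR and lipid droplet genes at 97. These were the most extreme of the lists, and the others ran from 14.5 to 90.5.

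**Figure D1:**
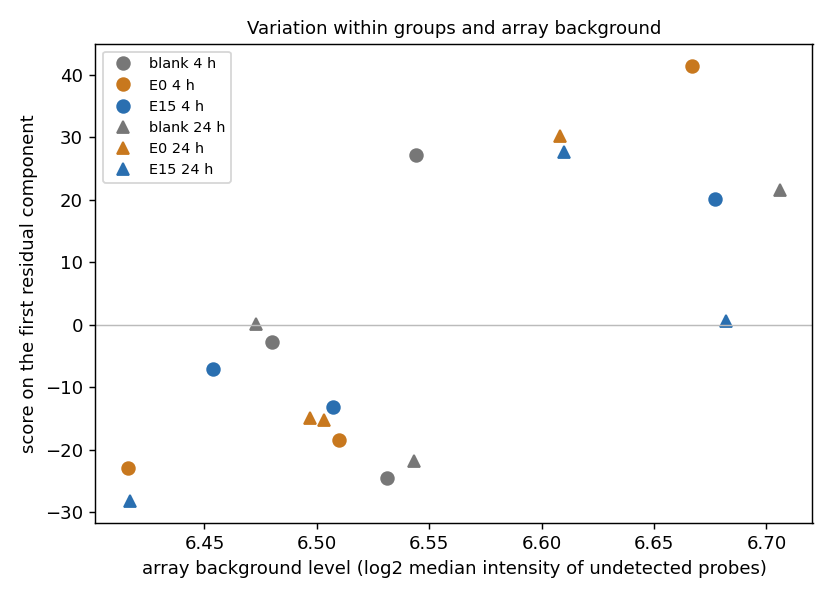
Score of each of the 18 arrays on the first component of the variation within groups (vertical axis) against the log2 background intensity of the array (horizontal axis), with circles for 4 h and triangles for 24 h. The scores ran from -28.2 to 41.4 and correlated with this background level at r = 0.727.

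The first comparison asked which transcripts had responded to the E0 extract after 4 h. Antioxidant genes under NRF2, a regulator of the response to oxidative stress, rose as a group, with 17 of 19 members positive and a mean log2 fold change of 0.55 (camera adjusted p = 2.32e-11, and adjusted p = 0.0275 with an estimated correlation). Among them, heme oxygenase HMOX1 stood at 1.60 (SE 0.41), thioredoxin reductase TXNRD1 at 1.39 (SE 0.33) and AKR1C2 at 1.28 (SE 0.33), with n = 3 per group. Targets of the aryl hydrocarbon receptor, which senses polycyclic aromatic hydrocarbons, rose as well (9 of 10 positive, mean 0.45, adjusted p = 1.36e-06, and adjusted p = 0.00324 with an estimated correlation), and TIPARP stood at 1.18 (SE 0.27), CYP1A1 at 0.65 (SE 0.39) and CYP1B1 at 0.53 (SE 0.26). CYP1A1 ranged from 0.43 without blank 4 h replicate 1 to 0.99 without blank replicate 3, and CYP1B1 stood at 0.33 without E0 4 h replicate 1. Cholesterol synthesis genes fell, with 12 of 13 members negative and a mean of -0.46 (adjusted p = 6.58e-08; adjusted p = 0.00424 with an estimated correlation); HMGCS1, which makes the precursor of mevalonate, stood at -1.02 (SE 0.24).

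Hypoxia response genes were lower with a mean of -0.23 with E0 at 4 h (10 of 13 negative, adjusted p = 0.00321; adjusted p = 0.0466 with an estimated correlation), with the glycolytic regulator PFKFB4 at -1.0 (SE 0.30). Without E0 4 h replicate 3 the hypoxia list had an adjusted p of 0.125. Interferon response genes were lower with a mean of -0.27 (14 of 17 negative, adjusted p = 0.00166; adjusted p = 0.218 with an estimated correlation, and 0.161 without blank 4 h replicate 1). The fixed cytokine genes IL6 and CXCL8 had values of -1.14 (SE 0.45) and -1.40 (SE 0.55), and IL1B had 0.44 (SE 0.37), none of them called. IL6 stood at -0.53 without blank 4 h replicate 3, and IL1B at 0.14 without E0 4 h replicate 3 and 0.72 without E0 replicate 2. No single gene was called by limma (0 genes, smallest adjusted p = 0.983), with 230 genes at an unadjusted p below 0.05 where 519 are due by chance. Adjusted over the list alone, 5 NRF2 genes, 1 aryl hydrocarbon receptor target (TIPARP), 2 cholesterol genes (HMGCS1 and INSIG1) and 2 hypoxia genes (PFKFB4 and ANKRD37) passed. So did CSF3 (0.70, detected in 1 of 3 blank arrays) and CXCL1 (-1.46) of the cytokines and DDIT4 (-0.72) of the integrated stress response, lists that were not called with E0 at 4 h.

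With the E15 extract at 4 h, 3 genes fell and 0 rose. HMGCS1 fell 3.51-fold (log2 fold change -1.81, SE 0.24, adjusted p = 0.00742), INSIG1, a sterol sensor that restrains the cholesterol pathway, fell 3.36-fold (-1.75, SE 0.29, adjusted p = 0.0325), and BHLHE40, a transcriptional repressor, fell 4.07-fold (-2.03, SE 0.32, adjusted p = 0.0325). In each, all 3 E15 arrays lay below all 3 blank arrays. A second probe of INSIG1 gave -0.54. Cholesterol synthesis genes fell as a group (11 of 13 negative, mean -0.66, adjusted p = 7.85e-10; adjusted p = 0.00198 with an estimated correlation), 8 of them past the threshold adjusted over the list alone, while SQLE at -0.84 (adjusted p = 0.462) and SC5D at -1.12 (adjusted p = 0.934) were not called over all genes.

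NRF2 genes rose as a group with E15 at 4 h (15 of 19 positive, mean 0.39, adjusted p = 1.38e-05; adjusted p = 0.134 with an estimated correlation), with HMOX1 at 1.61 (SE 0.41, adjusted p = 0.462) and TXNRD1 at 1.39 (SE 0.33). Aryl hydrocarbon receptor targets rose by a mean of 0.43 (adjusted p = 1.63e-05; adjusted p = 0.00566 with an estimated correlation), with TIPARP at 1.15 (SE 0.27) and CYP1A1 at 0.70 (SE 0.39). Hypoxia genes fell with a mean of -0.31 (adjusted p = 0.00744, and adjusted p = 0.0627 with an estimated correlation), with PFKFB4 at -1.62. Heat shock proteins rose by a mean of 0.30 (9 of 12 positive, adjusted p = 0.0217; adjusted p = 0.259 with an estimated correlation); the adjusted p was 0.0661 without E15 4 h replicate 2 and 0.121 without blank 4 h replicate 3. At an unadjusted p below 0.05, 413 genes stood where 519 are due by chance. The 3 calls were lost (0 genes) without any of the E15 4 h arrays or without blank 4 h replicate 2 or 3, and 4 genes were called without blank 4 h replicate 1, the fourth being PFKFB4 (-1.93, adjusted p = 0.0166), named after its value was seen. With the first residual component as a covariate, which leaves fold changes as they are and changes only the errors, 13 genes were called, 6 higher and 7 lower. The calls also ended under median scaling (0 genes) and with only the compared groups in the fit (0 genes).

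After 24 h, the E0 extract raised 11 genes and lowered 3. The largest rise in log2 fold change was in ANGPTL4, a secreted inhibitor of lipoprotein lipase (9.49-fold, log2 3.25, SE 0.41, adjusted p = 0.00152), followed by the neuronal pentraxin NPTX1 (8.10-fold, 3.02, SE 0.34, adjusted p = 0.000473). CYP1A1 and CYP1B1, cytochromes that oxidise polycyclic aromatic hydrocarbons, rose at least 3.92-fold (measured log2 difference 2.38, SE 0.39, adjusted p = 0.0135) and 3.01-fold (1.59, SE 0.26, adjusted p = 0.0135). The interleukins IL1A and IL1B rose 4.48-fold (2.16, SE 0.36) and 3.92-fold (1.97, SE 0.37), and the growth factor response genes IER3 and FOSL1 rose 4.02-fold (2.01, SE 0.30) and 3.13-fold (1.65, SE 0.24). The amino acid transporter subunit SLC3A2 rose by 1.10 (SE 0.21), SHISA2 by 1.73 (SE 0.30) and AKR1C4 by 1.68 (SE 0.33). Probes of the AKR1C family can bind its close paralogs, so that AKR1C4 is uncertain. OLFML2A fell by 2.06 on the log2 scale (SE 0.37, 4.17-fold), PRICKLE1 fell by 1.76 (SE 0.29, 3.39-fold) and the mitochondrial coactivator PPARGC1A fell by 1.36 (SE 0.25, 2.58-fold). For each gene named by the rule, all 3 arrays of one group lay beyond all 3 of the other. The 3 probes of ANGPTL4 ranged from 0.73 to 3.25. CYP1A1 was not above background in the 24 h blank, hence its lower bound.

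Grouped by the fixed lists, aryl hydrocarbon receptor targets rose with E0 at 24 h (9 of 10 positive, mean 0.93, 2 called, 7 adjusted over the list alone; adjusted p = 2.32e-11; adjusted p = 0.000764 with an estimated correlation), with TIPARP at 1.08 (adjusted p = 0.28) and NQO1 at 0.91 (adjusted p = 0.359) not called singly. NRF2 genes rose (17 of 19 positive, mean 0.60, 6 adjusted over the list alone; adjusted p = 1.24e-09; adjusted p = 0.0463 with an estimated correlation), with AKR1C2 at 1.60, SLC7A11 at least 1.56-fold above the blank, which was not above background (measured log2 difference 1.06), and HMOX1 at 0.68 (0.22 without E0 24 h replicate 3). Immediate early and MAPK feedback genes rose (13 of 15 positive, mean 0.70, 2 called; adjusted p = 1.65e-08, and adjusted p = 0.0627 with an estimated correlation). PPAR and lipid droplet genes rose by a mean of 0.69 (5 of 7 positive; adjusted p = 0.00211; adjusted p = 0.163 with an estimated correlation), with ANGPTL4 the called member and PLIN2 at 0.75 (0.44 without E0 24 h replicate 3). Cytokines had a mean of 0.44 and a median of 0.15 (11 of 14 positive; adjusted p = 0.00221, and adjusted p = 0.337 with an estimated correlation), with IL6 at 0.03 and CXCL8 at -0.17, both of which changed sign when 1 array was left out. Cholesterol genes fell with a mean of -0.37 (12 of 13 negative; adjusted p = 0.000766; adjusted p = 0.0466 with an estimated correlation). Mitotic genes were lower in 20 of 20 members (mean -0.38, adjusted p = 0.000313, and adjusted p = 0.369 with an estimated correlation), while MKI67 alone stood at -0.20 and changed sign without E0 24 h replicate 3. Interferon genes were lower (mean -0.30, adjusted p = 0.00726, and adjusted p = 0.337 with an estimated correlation) and p53 genes higher (mean 0.36, 10 of 15 positive, adjusted p = 0.0254, and adjusted p = 0.369 with an estimated correlation), with GDF15 at 1.95 (adjusted p = 0.799), or 0.62 without E0 24 h replicate 3.

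At an unadjusted p below 0.05, 644 genes stood at 24 h with E0 where 519 are due by chance. Leaving out E0 24 h replicate 1, 2 or 3 gave 12, 8 or 6 called genes in place of 14, and leaving out blank 24 h replicate 1, 2 or 3 gave 4, 4 or 7. Of these, 5, 1 and 0 were lower without the E0 replicates, and 0 without any blank replicate. ANGPTL4 and NPTX1 were called with E0 in 6 of 6 such fits, IER3 and FOSL1 in 5, CYP1B1, IL1A, SHISA2 and PRICKLE1 in 2, and CYP1A1, IL1B, AKR1C4, OLFML2A and PPARGC1A in 1. Without E0 24 h replicate 3 the mean was 0.23 for cytokines (adjusted p = 0.175), 0.09 for p53 genes (adjusted p = 0.739), -0.18 for mitotic genes (adjusted p = 0.148) and -0.14 for interferon genes (adjusted p = 0.281). In that array GDF15 had a level of 10.51, against 6.63 and 6.37 in the other E0 arrays, and CDKN1A had 12.14 against 10.63 and 10.33. The adjusted p of p53 genes was 0.0731 without blank 24 h replicate 2 and 0.0655 without blank replicate 3, and that of interferon genes was 0.055 without blank replicate 1 and 0.0573 without blank replicate 2.

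The E15 extract raised 13 genes and lowered 12 at 24 h, 24 of the 25 by at least 2-fold. ANGPTL4 rose 12.8-fold (log2 3.68, SE 0.41, adjusted p = 0.000246) and NPTX1 rose 9.81-fold (3.29, SE 0.34, adjusted p = 0.000126). IL1A rose 6.14-fold (2.62, SE 0.36, adjusted p = 0.00269) and IL1B rose 4.68-fold (2.23, SE 0.37, adjusted p = 0.0122), both agonists of the interleukin-1 receptor. The aryl hydrocarbon receptor targets CYP1A1, CYP1B1 and TIPARP rose at least 3.01-fold (measured log2 difference 2.01, SE 0.39), 3.29-fold (1.72, SE 0.26) and 2.92-fold (1.55, SE 0.27). IER3 rose 3.99-fold, FOSL1 3.27-fold and SHISA2 3.21-fold, and SLC3A2, POLR3E and RNF175 by 1.06, 1.15 and 1.11 on the log2 scale (SE 0.21, 0.22 and 0.22). The 3 probes of ANGPTL4 ranged from 0.40 to 3.68. NPTX1, IL1A and RNF175 were detected in 2 of 3 blank arrays at 24 h.

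Of the 12 genes that fell with E15 at 24 h, HMGCS1 and MVD (2 genes) are members of the cholesterol list. HMGCS1 fell by 1.61 on the log2 scale (SE 0.24, 3.06-fold, adjusted p = 0.00504) and the decarboxylase MVD fell by 1.43 (SE 0.27, 2.69-fold, adjusted p = 0.0296). The sterol reductase TM7SF2 fell by 1.64 (SE 0.28, 3.11-fold, adjusted p = 0.0166) and the mitochondrial citrate carrier SLC25A1 fell by 1.18 (SE 0.22, 2.26-fold, adjusted p = 0.0235). The inhibitor of differentiation ID3 fell 4.16-fold (-2.06, SE 0.37) and the scavenger receptor SCARA3 fell 3.31-fold (-1.73, SE 0.29). A second SCARA3 probe gave -0.67. PRICKLE1 (-1.51), PPARGC1A (-1.33), DENND2A (-1.32), IRX3 (-1.16) and the histone gene H2AC19 (-1.50) also fell, as did FAM181B by at least 1.57-fold (measured log2 difference -0.94), which was not above background with E15; histone genes of this family have near-identical copies, so that H2AC19 is uncertain. DENND2A and H2AC19 were detected in 2 of 3 E15 arrays. The genes SLC3A2, POLR3E, RNF175, IRX3 and FAM181B fall outside the naming rule and were chosen after their values were seen.

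**Figure D2:**
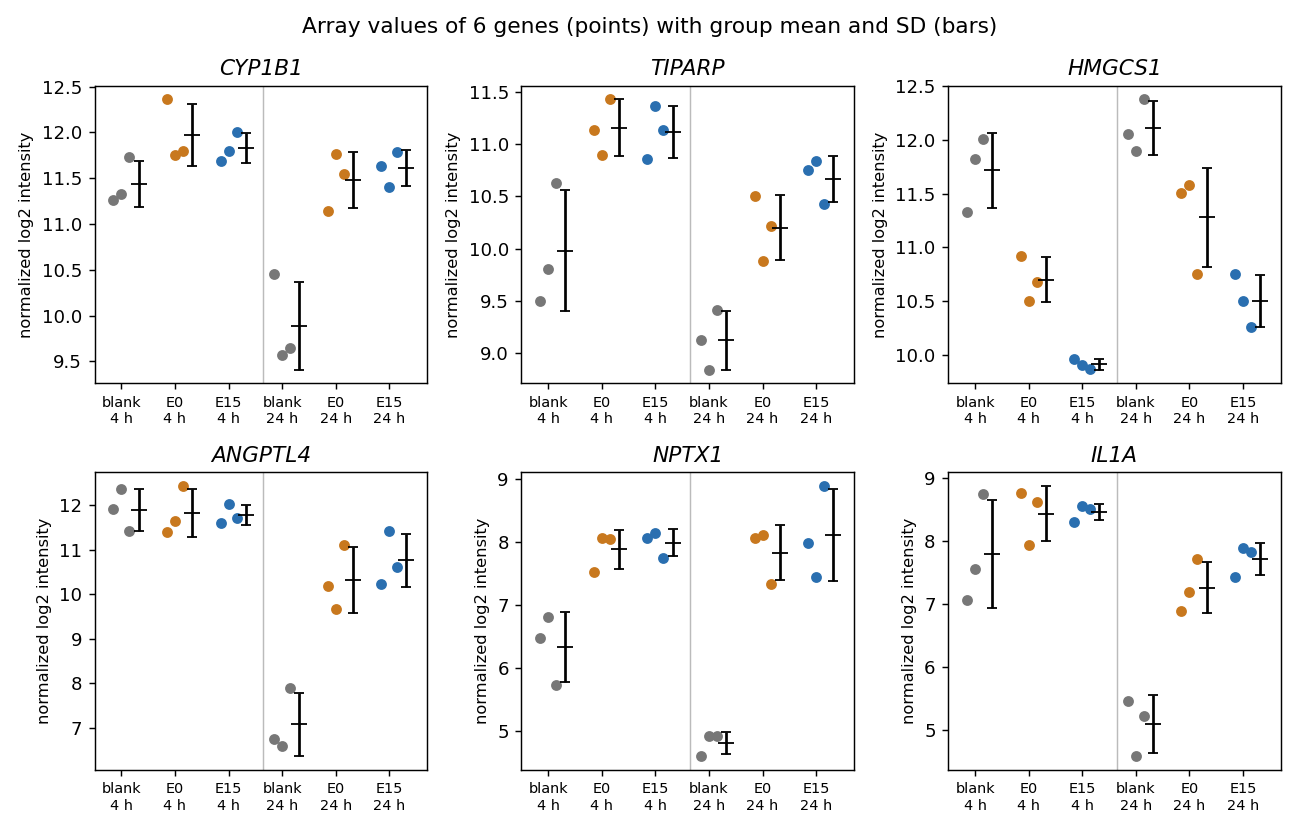
Normalized log2 level of CYP1B1, TIPARP, HMGCS1, ANGPTL4, NPTX1 and IL1A in each array (points) of the 6 groups, with the group mean and SD beside the points (n = 3). In the 24 h blank ANGPTL4 had a mean of 7.08 ± 0.71, against 10.32 ± 0.73 with E0 and 10.76 ± 0.60 with E15.

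By list, cholesterol synthesis genes fell with E15 at 24 h (12 of 13 negative, mean -0.78, 2 called, 8 adjusted over the list alone; adjusted p = 7.70e-10; adjusted p = 0.00198 with an estimated correlation), with LSS at -0.96 (adjusted p = 0.304) and NSDHL at -0.92 (adjusted p = 0.133) not called singly. Aryl hydrocarbon receptor targets rose (9 of 10 positive, mean 0.92, 3 called, 6 adjusted over the list alone; adjusted p = 1.24e-09; adjusted p = 0.00106 with an estimated correlation). Metallothioneins, which bind zinc and copper, were higher in 8 of 8 members (mean 0.59; 2 adjusted over the list alone, MT1H and MT1M; adjusted p = 0.000225; adjusted p = 0.0368 with an estimated correlation). Immediate early genes rose (13 of 15 positive, mean 0.79, 7 adjusted over the list alone; adjusted p = 3.04e-08, and adjusted p = 0.0627 with an estimated correlation), with EGR1 at 1.95 (adjusted p = 0.238) and DUSP5 at 1.35 (adjusted p = 0.117). NRF2 genes rose (17 of 19 positive, mean 0.56; adjusted p = 3.00e-07; adjusted p = 0.0757 with an estimated correlation), with SLC7A11 at least 1.79-fold above the blank, which was not above background (measured log2 difference 1.25), and GCLM at 0.90 (0.56 without blank 24 h replicate 2). Cytokines rose (13 of 14 positive, mean 0.71, median 0.26; adjusted p = 5.53e-06; adjusted p = 0.108 with an estimated correlation), with IL24 at least 3.19-fold above the blank, also not above background (measured log2 difference 2.02, adjusted p = 0.233), and CXCL8 at 0.62, or -0.12 without E15 24 h replicate 2. PPAR and lipid droplet genes rose (6 of 7 positive, mean 0.85, adjusted p = 0.000158, and adjusted p = 0.0778 with an estimated correlation). ANGPTL4 was the called member at 3.68, and the others named by the rule, CPT1A, ACADVL and PDK4, stood at 0.61, 0.51 and 0.43. Genes of the integrated stress response rose by a mean of 0.52 (12 of 16 positive, adjusted p = 0.00211, and adjusted p = 0.508 with an estimated correlation), with the amino acid synthesis genes ASNS at 1.66 and PSAT1 at 1.58. Mitotic genes were lower in 20 of 20 members (mean -0.41, adjusted p = 0.000437, and adjusted p = 0.369 with an estimated correlation), and interferon genes were lower with a mean of -0.39 (14 of 17 negative, adjusted p = 0.000491; adjusted p = 0.164 with an estimated correlation).

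At an unadjusted p below 0.05, 813 genes stood at 24 h with E15 where 519 are due by chance. Without E15 24 h replicate 1, 2 or 3 the count of 25 became 13, 8 or 9, and without blank 24 h replicate 1, 2 or 3 it became 6, 10 or 13. Of these, 6, 1 and 1 were lower without the E15 replicates and 1, 4 and 2 without the blank replicates, in place of 12. ANGPTL4, NPTX1, IL1A, CYP1B1, FOSL1 and HMGCS1 were called with E15 in 6 of 6 such fits and IER3 in 5. By contrast, MVD, PRICKLE1 and SLC25A1 were called in 0 of them, and the other genes named by the rule in 1 or 2. Without E15 24 h replicate 2 the mean was -0.19 for mitotic genes (adjusted p = 0.263) and 0.20 for the integrated stress response (adjusted p = 0.202). In that array DDIT3 had a level of 9.42, against 6.38 and 6.18 in the other E15 arrays, and GDF15 had 9.79 against 6.25 and 7.17.

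Across 10383 genes, the log2 fold changes of the 2 extracts correlated at r = 0.684 (Spearman 0.639) at 4 h and 0.689 (Spearman 0.605) at 24 h. Genes are not independent replicates, and both comparisons use the same blank arrays. Simulated groups with no effect against shared blanks gave a median of 0.555 at 4 h (range -0.378 to 0.958 over 100 draws) and 0.553 at 24 h (-0.429 to 0.951). The covariance was 0.0519 against a simulated 0.0481 at 4 h and 0.076 against 0.0431 at 24 h, differences of 0.00379 and 0.0328. Both lay inside the simulated ranges of -0.0428 to 0.29 and -0.0535 to 0.249. Of the genes that rose at 24 h, 11 with E0 and 13 with E15, 10 were shared, where independent lists would share 0.0138. Of those that fell, 3 and 12, the shared ones were PRICKLE1 and PPARGC1A (2 genes, 0.00347 for independent lists). Simulated arrays with no effect against shared blanks had a median of 0 shared genes in each direction. Over 100 draws the highest was 0 rises and 2 falls when arrays were drawn with repeats, and 1 and 0 without repeats. The independent value leaves out the shared blanks and the simulated one leaves out the effects, so neither gives the size of a shared effect. The 3 blank arrays of a time cannot be split into parts of at least 2 arrays each, so part of the excess may come from the shared controls.

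The direct comparison of the fuels asked whether the ethanol blend changed the response. At 24 h, metallothioneins were higher with E15 than with E0 (7 of 8 members, mean 0.65; camera adjusted p = 6.58e-07; adjusted p = 0.00696 with an estimated correlation), with MT1H at 1.26 (SE 0.38, detected in 1 of 3 E0 arrays), MT1M at 1.20 (SE 0.26) and MT1F at 1.13 (SE 0.28), the 3 that passed adjusted over the list alone (p = 0.0103, 0.00186 and 0.00277). MT2A stood at -0.04 (SE 0.18) and changed sign without E15 24 h replicate 3. Metallothionein genes are close paralogs, and probes can share signal between them. Cholesterol synthesis genes were lower with E15 (12 of 13 members, mean -0.41; adjusted p = 3.02e-05; adjusted p = 0.019 with an estimated correlation), with MVD at -1.0 (SE 0.27) and HMGCS1 at -0.78 (SE 0.24), the 2 that passed adjusted over the list alone (p = 0.0213 and 0.0335). All 3 arrays of E15 lay beyond all 3 of E0 for 4 of 8 metallothioneins and 3 of 13 cholesterol genes, where chance gives 10% for a single gene. Members of a list share the same 6 arrays and are not independent, and the share over all genes was not counted. These counts are therefore no test of the lists. Both lists kept their calls when any 1 of the 6 arrays was left out, with a largest adjusted p of 0.000102 and 0.00201.

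No single gene differed between the fuels by limma at 24 h (0 genes, smallest adjusted p = 0.999; 347 genes at an unadjusted p below 0.05) or at 4 h (0 genes; 122 genes at an unadjusted p below 0.05), with 519 due by chance each time. CYP1A1 differed by -0.38 (SE 0.39) and CYP1B1 by 0.13 (SE 0.26) at 24 h, ANGPTL4 by 0.44 (SE 0.41) and IL1A by 0.46 (SE 0.36), all with an adjusted p of 0.999. CYP1A1 changed sign without E15 24 h replicate 2 (0.02) and CYP1B1 without E0 24 h replicate 1 (-0.05). ANGPTL4 stood at 0.11 without E15 replicate 2 and 0.83 without E0 replicate 3, and IL1A at 0.27 without E0 replicate 1. Without E0 24 h replicate 1, 1 gene was called, the small nucleolar RNA SNORA12 (2.05, adjusted p = 0.0338), named after its value was seen. Cytokines had a mean difference of 0.28 at 24 h (adjusted p = 0.0419, and adjusted p = 0.508 with an estimated correlation), with adjusted p of 0.354 and 0.403 without E0 replicate 1 and 2, and 0.858 without E15 replicate 2. The mean was 0.13 without E0 replicate 2 and 0.03 without E15 replicate 2.

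At 4 h, 5 lists differed between the fuels with the preset correlation and 0 with an estimated one. Metallothioneins were higher with E15 in 8 of 8 members (mean 0.31, adjusted p = 0.00217; adjusted p = 0.0656 with an estimated correlation), and 0.0579 without E0 4 h replicate 3. Cholesterol genes were lower (mean -0.20, adjusted p = 0.00901; adjusted p = 0.108 with an estimated correlation), with INSIG1 at -0.85, and their adjusted p was 0.0681, 0.0522 and 0.0578 without E0 4 h replicate 1, E0 replicate 3 and E15 replicate 2. Genes of the integrated stress response were lower (mean -0.34, adjusted p = 0.00211, and adjusted p = 0.508 with an estimated correlation), and 0.414 without E0 4 h replicate 1 (mean -0.15). Immediate early genes had a mean of 0.16 (adjusted p = 0.0347, and adjusted p = 0.508 with an estimated correlation) and cytokines 0.16 (adjusted p = 0.0429, and adjusted p = 0.508 with an estimated correlation). Leaving out E0 replicate 1, 2 or 3 or E15 replicate 2 or 3 ended both, with adjusted p from 0.053 to 0.336 for cytokines and 0.0545 to 0.269 for immediate early genes. In those fits the means ran from 0.08 to 0.28 for cytokines and from 0.10 to 0.24 for immediate early genes.

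**Figure D3:**
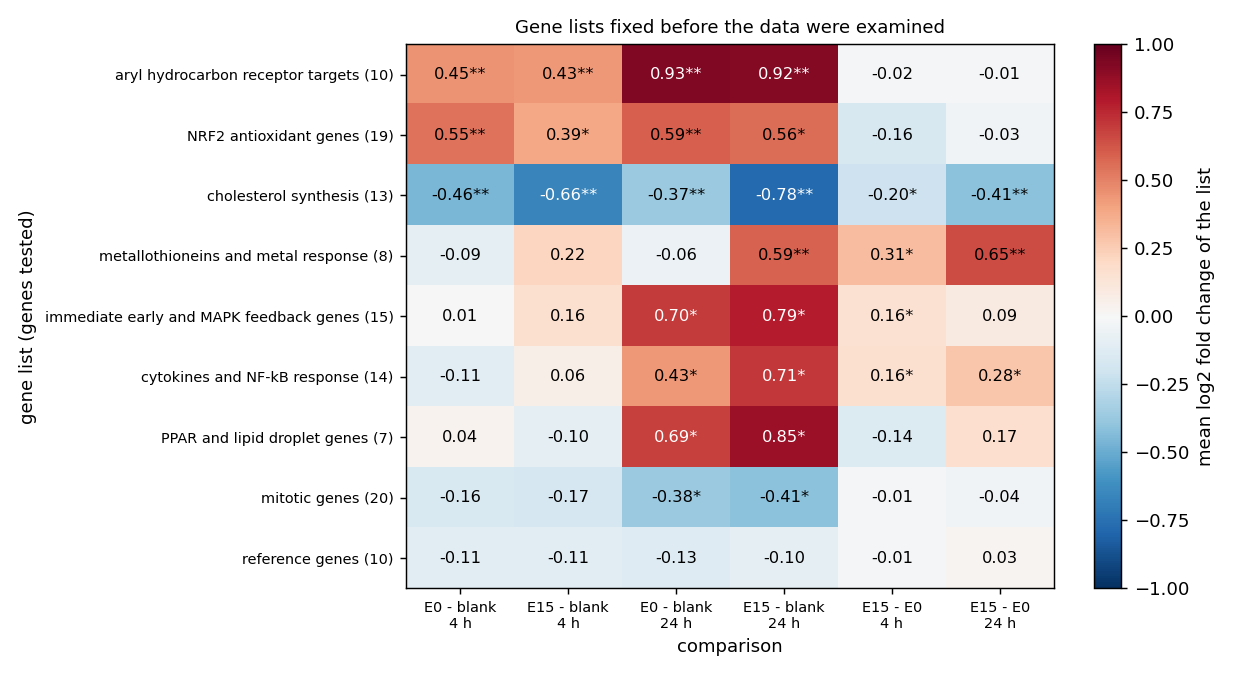
Mean log2 fold change of 9 gene lists (rows) in 6 comparisons (columns), with 1 asterisk where the camera adjusted p was below 0.05 and a pair of asterisks where it also was with an estimated correlation. In E15 against E0 at 24 h, metallothioneins had a mean of 0.65 and cholesterol synthesis genes -0.41.

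In the blank wells, levels also differed between the times, with 59 genes lower and 18 higher at 24 h than at 4 h, 65 of the 77 by at least 2-fold when genes not above background in one group are taken at their lower bound. The genes named here were chosen after their values were seen. ANGPTL4 fell 28.1-fold (log2 -4.81, SE 0.41, adjusted p = 7.83e-06; 3 probes from -4.81 to -1.93), the chemokine CXCL8 12.7-fold (-3.67, SE 0.55, adjusted p = 0.00305; second probe -1.36), HMOX1 8.98-fold (-3.17, SE 0.41, adjusted p = 0.000916) and the immediate early factor EGR1 8.44-fold (-3.08, SE 0.55, adjusted p = 0.0104). IL1A fell 6.46-fold (-2.69, SE 0.36, adjusted p = 0.000916). TMEM187 rose 3.35-fold (1.74, SE 0.23, adjusted p = 0.000916), the receptor ERBB3 2.71-fold (1.44, SE 0.28, adjusted p = 0.0186, detected in 2 of 3 blank arrays at 4 h), and C1orf115 at least 2.11-fold. List tests of this comparison were added after seeing the data. In them immediate early genes fell (mean -1.45, 8 called, adjusted p = 6.29e-21; adjusted p = 0.0202 with an estimated correlation), as did cytokines (mean -1.24, adjusted p = 4.17e-12; adjusted p = 0.0466 with an estimated correlation) and aryl hydrocarbon receptor targets (mean -0.56, adjusted p = 0.000461; adjusted p = 0.0366 with an estimated correlation). The count of 77 became 31 or 53 without blank 4 h replicate 1 or 2, 20 or 27 without blank 24 h replicate 1 or 2, and 83 and 57 without the third replicate of either time. The 18 higher genes became 1 without blank 4 h replicate 1, and 1, 2 and 8 without blank 24 h replicates 1, 2 and 3.

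The response to E15 differed between 24 h and 4 h in 1 gene. ANGPTL4 had a log2 difference of 3.79 (SE 0.58, adjusted p = 0.0406), since E15 stood at -0.11 against the blank at 4 h and at 3.68 at 24 h. For E0 the same difference was 3.31 (SE 0.58, adjusted p = 0.22) and no gene was called by limma (0 genes; 276 at an unadjusted p below 0.05, 519 due by chance). The call in E15 held in 2 of 12 fits that left out 1 array, those without E15 24 h replicate 1 and without blank 24 h replicate 3, and the largest adjusted p of the other fits was 0.239. BHLHE40, with 2.71 (adjusted p = 0.068), was called in its place without blank 4 h replicate 1 (adjusted p = 0.0194), and was named after its value was seen. ANGPTL4 passed for E0 without blank 24 h replicate 3 (adjusted p = 0.0463). The difference between E15 and E0 did not change between times in any gene by limma (0 genes; 222 at an unadjusted p below 0.05).

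The remaining lists were not called in the 6 planned comparisons. The smallest adjusted p was 0.0922 for xenobiotic phase I and II enzymes (E15 against E0 at 24 h), 0.0503 for DNA replication genes (E15 at 4 h), 0.217 for the TGF-beta and extracellular matrix list and 0.27 for reference genes (mean -0.13 with E0 at 24 h). Markers of other cell types gave 0.065 for 5 squamous and basal keratinocyte genes (mean -0.62 with E15 at 24 h), 0.0945 for 2 fibroblast markers and 0.194 for 3 immune cell markers. Of 16 airway markers, 14 did not pass the detection filter and 2 had no probe listed. Of the fixed genes, AHRR and PTGS2 did not pass the detection filter (detected in at most 0 and 1 of 18 arrays). CDKN1A stood at 0.17 and 0.59 with E0 and at -0.12 and 0.61 with E15 at 4 h and 24 h. DDIT3 stood at 0.57 and 0.48 with E0 and at -0.26 and 0.56 with E15. ATF3 stood at -0.21 and 0.15 with E0 and at -0.50 and 0.78 with E15, and none of the 3 was called. ALDH3A1 stood at 0.41 and 1.22 with E0 and at 0.25 and 1.01 with E15, also not called. DDIT3 changed sign in all 4 comparisons when 1 array was left out. In blank 4 h replicate 3 it had a level of 8.87, against 4.90 and 6.66 in the other blank arrays, and ATF3 had 8.06 against 4.99 and 5.10. At 24 h it stood at -0.34 without E0 replicate 3 and at -0.48 without E15 replicate 2. ATF3 changed sign in 3 of the 4, with -0.37 at 24 h without E0 replicate 3, and its 0.78 became 0.13 without E15 replicate 2. CDKN1A changed sign with both extracts at 4 h, and at 24 h it stood at 0.04 without E0 replicate 3 and 0.16 without E15 replicate 2. ALDH3A1 changed sign with E15 at 4 h (-0.08 without blank replicate 3), and at 24 h it stood at 1.89 without E0 replicate 3 and 1.55 without E15 replicate 2. Of 65 printed values of genes not called that were checked in this way, 17 changed sign and 33 changed sign or moved by over 1.5 times.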

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

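The tests of late levels against the 4 h blank and against E15 at 4 h, the splits with group means removed, and the counts of splits for single lists and with an estimated correlation, were chosen only after the results were seen. ANGPTL4 stood out because its response to E15 differed between 24 h and 4 h by 3.79 on the log2 scale (SE 0.58, limma adjusted p = 0.0406). The call held in 10 of 28 alternatives, with adjusted p from 0.000791 to 0.917. Of the fits without 1 array it held in those without E15 24 h replicate 1 or blank 24 h replicate 3, and was lost in the other 10 of 12. Probes with no gene name are not used in the comparisons of genes. Of 3933 such probes, 11 differed between the 24 h and 4 h blanks when 17388 probes were tested (4 higher, 7 lower), and 0 did in either extract's comparisons with the blank by limma. Groups of 3 arrays were not tested for single arrays standing apart.

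Of the 13 genes that rose with E15 at 24 h, 9 were among the 59 that were lower in the blank at 24 h than at 4 h: ANGPTL4, CYP1B1, FOSL1, IER3, IL1A, IL1B, NPTX1, SHISA2 and SLC3A2. Chance values of the shared 24 h blank arrays are argued against, since 100 simulations with no change of the blank gave at most 4 such genes, although these resampled arrays with repeats and called a median of 99 genes as higher. A slower decline of early genes in cells given the extract was the biological explanation tested, and 5 of the 9 means with E15 at 24 h lay above the 4 h blank, which met the bound first written against it. That bound took no account of error: of those 5 only NPTX1 (1.77, SE 0.34) lay above by over 1 SE, while ANGPTL4 (-1.13, SE 0.41), FOSL1 (-0.36, SE 0.24) and IER3 (-0.65, SE 0.30) lay below by over 1 SE, and the requirement of 1 SE was added after these values were seen. A net rise above the 4 h level in cells given the extract is argued against for these 9 genes. With E15, 0 of them were higher at 24 h than at 4 h by over 1 SE and 6 were lower. The genes were picked for a fall in the blank, and no time between 4 h and 24 h was measured. A later rise that stayed below the 4 h level thus cannot be told apart from a slower decline. The slower decline stays open, as NPTX1 changed by 0.12 (SE 0.34) and already stood 1.65 (SE 0.34) above the blank at 4 h.

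Other splits of the same arrays into groups were fitted in the same way. For comparisons of 3 against 3 arrays, 10 splits are too few for a share below 0.05. The real count of genes and the highest of the other splits were 0 and 0 for E0 at 4 h, 3 and 0 for E15 at 4 h, 14 and 0 for E0 at 24 h, and 25 and 0 for E15 at 24 h. They were 0 and 2 for E15 against E0 at 4 h, 0 and 0 at 24 h, and 77 and 0 for the blank between times. For the E15 response between times chance cannot be excluded by these splits, since 12 of 100 gave at least its 1 gene (highest other 8). The splits still carry effects of treatment, as 11 of the 99 others had calls and 0 of them did with the real group means removed. The real counts were 0 for the E0 response (highest other 5) and for the difference between fuels (highest other 51). All 100 splits reach a count of 0, so those splits tested nothing. A split with 51 calls points to a structure of the arrays. Arrays were regrouped only within each time, and with the real group means removed the same split had 403 calls. Its difference in the first residual component ranked 1 among 99 splits. Chance cannot be excluded either for the correlations between the extracts, which 18 of 100 splits reached at 4 h (0.684, highest other 0.819) and 14 of 100 at 24 h (0.689, highest other 0.825).

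For the total number of list calls chance is argued against, since the real split alone (1 of 100) reached 37 calls, with 33 as the highest of the others. A share of 1 of 100 is the smallest that these splits can give, and it does not exclude chance for any single list. The other splits had a median of 14 calls, but they still carry effects of treatment. With the real group means removed the same splits had a median of 4 calls and a highest of 29 with the preset correlation (72 of 99 had any) and a median of 0 with an estimated one (1 of 99, highest 2). With an estimated correlation the real split gave 14 calls, against a median of 0 and a highest of 3. For single lists, 23 of the 37 calls had a p as small in fewer than 5 of 100 splits and 14 did not. Among the latter were mitotic genes at 24 h (23 splits with E0, 30 with E15), interferon genes at 24 h (21 and 7), and the integrated stress response with E15 at 24 h (25). For E0 at 24 h, p53 genes (24), cytokines (17) and cholesterol genes (15) were among them too. Between the fuels they were cytokines at 24 h (36) and, at 4 h, the integrated stress response (21), cholesterol genes (14) and immediate early genes (8). NRF2 genes with E15 at 4 h (6) and immediate early genes with E15 at 24 h (5) made up the rest.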

How the results depend on the processing

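The covariates for the first residual component and for the array background level, and the fit without the 5 arrays scoring over 1 SD (23.2) on the first principal component, were chosen only after the data were seen. NPTX1 and ANGPTL4 at 24 h kept their calls with both extracts in 21 of 21 and 22 of 22 settings, and HMGCS1 with E15 at 24 h in 21 of 22. CYP1A1, near background, kept its call in 10 of 21 with E0 and 7 of 21 with E15. The aryl hydrocarbon receptor and cholesterol lists against the blank, and metallothioneins and cholesterol genes between fuels at 24 h, kept theirs in 19 of 19. Of named gene values, called or not, 2868 stayed on their side of the threshold, 283 became weaker, 16 stronger and 0 reversed. A change of sign with no call on either side counted as stayed, and the 283 are all calls lost. Of 37 calls of named genes, 6 were kept with median scaling, 11 without the 5 arrays and 17 with only the groups compared. Array weights and trended variance each kept 37 of 37. Of list values, 626 stayed, 76 became weaker and 1 reversed, the cytokines for E15 against E0 at 24 h (mean -0.0395 without the 5 arrays). Median scaling moved the median of all genes to 0.11 for E15 at 4 h, -0.14 for E15 at 24 h and 0.11 for the blank between times, and to -0.14, -0.26 and -0.13 for the E0, E15 and between-fuel interactions, so changes under it are relative to these. Under it the 37 list calls held, and the share of higher calls went from 52% to 75% for E15 and from 78.6% to 100% for E0 at 24 h. Array weights, trended variance, single probes and only the groups compared were not run for the lists, and the chip block was not run. The first residual component comes from the residuals of the same model, so as a covariate it could change the SE but no fold change. Calls kept or gained under it thus carry no weight for the genes. The cause of the other moves below was not tested.

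For E15 at 4 h (3 genes), the count was 5 with no background correction, an offset of 50, the authors' values or the background covariate. It was 0 with median scaling, only the groups compared or without the 5 arrays, 1 with no filter or every probe on its own, and 13 (6 higher, 7 lower) with the residual component. For E0 at 24 h (14 genes) it was 7 with no background correction or the authors' values, and 9 with an offset of 50 or every probe on its own. It was 2 with median scaling, 8 with a detection p below 0.01, 6 with only the groups compared, 23 with array weights and 28 with the residual component. For E15 at 24 h (25 genes) it was 4 with median scaling or without the 5 arrays, 16 with a detection p below 0.01, 15 with every probe on its own and 11 with only the groups compared. Array weights gave 213 and the residual component 73. For the blank between times (77 genes) it was 7 with median scaling, 123 with cyclic loess, 30 with only the groups compared and 125 with array weights. The residual component gave 202, the background covariate 135, and leaving out the 5 arrays 28. For the E15 response between times (1 gene) it was 0 with no background correction, an offset of 50, median scaling, the authors' values, no filter, the mean of a gene's probes or every probe on its own. It was 2, with BHLHE40 as the second gene, under a detection p below 0.01, trended variance, array weights or the residual component. For the E0 response between times (0 genes) it was 1, ANGPTL4, with the residual component, the background covariate or without the 5 arrays. List calls numbered 14 with an estimated correlation in place of 37, and at most 44 over the alternatives other than leaving out 1 array.

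The replicate numbers did not pair the arrays. The deviations of 45 same-numbered pairs correlated at -0.57 to 0.564 (median -0.0379, 15 above 0.1), and 1 of 18 arrays correlated best with its own number. With the replicate block, the count was 1 for E15 at 4 h, 10 for E0 at 24 h, 16 for E15 at 24 h, 46 for the blank between times and 0 for the E15 response between times. Of the 37 calls of named genes 27 were kept with the block, and list calls numbered 37.

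Leaving out 1 array at a time gave 0 to 4 genes for E15 at 4 h, 4 to 12 for E0 at 24 h, 6 to 13 for E15 at 24 h, 0 to 1 for E15 against E0 at 24 h and 20 to 83 for the blank between times. It gave 0 to 1 for the E0 and the E15 response between times, 0 for the other counts of genes, and 32 to 42 list calls. The correlation between the extracts ranged from 0.508 to 0.785 at 4 h and from 0.553 to 0.757 at 24 h.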

Other observations

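List tests of the interactions and of the blank comparison, and the fits with the background level as a covariate, were chosen only after the data were seen. Between 4 h and 24 h the response to E15 moved upward in genes of the integrated stress response (15 of 16 positive, mean 0.74, camera adjusted p = 0.000331, and adjusted p = 0.45 with an estimated correlation). The hypoxia list moved the same way (10 of 13 positive, mean 0.38, adjusted p = 0.0358, and adjusted p = 0.164 with an estimated correlation). The 5 squamous and basal keratinocyte genes moved downward (4 of 5 negative, mean -0.77, adjusted p = 0.0317, and adjusted p = 0.45 with an estimated correlation). The difference between fuels changed between times in the integrated stress response (15 of 16 positive, mean 0.53, adjusted p = 0.00476, and adjusted p = 0.54 with an estimated correlation). For the interactions 4 lists were called for E0, 7 for E15 and 1 for the difference between fuels, and 0 of them with an estimated correlation.

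In the blank wells, metallothioneins were lower at 24 h than at 4 h in 8 of 8 members (mean -0.54, adjusted p = 0.00397, and adjusted p = 0.115 with an estimated correlation). The hypoxia list was lower (8 of 13 negative, mean -0.40, median -0.05, adjusted p = 0.00795, and adjusted p = 0.104 with an estimated correlation). Mitotic genes were higher in 19 of 20 members (mean 0.34, adjusted p = 0.0173, and adjusted p = 0.574 with an estimated correlation). Interferon genes were higher in 14 of 17 (mean 0.29, adjusted p = 0.0463, and adjusted p = 0.493 with an estimated correlation).

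At 24 h, cholesterol synthesis genes were lower and metallothioneins higher with E15 than with E0. A single array is argued against as the whole cause, since the largest adjusted p over 6 arrays left out in turn was 0.00201 for cholesterol genes and 0.000102 for metallothioneins. The background level is argued against too, since with it as a covariate the means were -0.38 in place of -0.41 (adjusted p = 6.97e-05, range over alternatives 3.66e-07 to 0.019) and 0.665 in place of 0.649 (adjusted p = 4.8e-07, range 2.56e-08 to 0.00696). With this covariate the first component of the variation within groups still held 28.8%. Mean weights on that component lay at percentile 3.55 for cholesterol genes and 14.5 for metallothioneins. Uneven differences between arrays beyond the background level thus stay open for both lists. A difference between the extracts of the fuels may underlie both, as a hypothesis found and tested on the same arrays, with 0 single genes called by limma (347 at an unadjusted p below 0.05). Signal shared between paralogous metallothionein probes was not tested and stays open.

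The first component of the variation within groups held 42.3% of the residual variance, and the replicate number explained 2.68% of its scores. Component weight and mean level had a Spearman rho of 0.109 across genes. This cannot decide whether the normalization left a bias with intensity. Quantile normalization gives all arrays the same distribution, so a low rho was largely fixed in advance. The weights of the 2 probes of a gene correlated at 0.0687 (95% interval 0.0194 to 0.124, 2066 genes), against 0.525 for the fold changes of the blank between times, which is consistent with effects on single probes and not on transcripts. With the background level as a covariate the first component still held 28.8%, between the bounds set for and against this explanation, so the background level stays open. For these 2066 genes, the low correlation of 0.0687 argues against transcript differences between the cell populations of the wells as the main source of the component. A smaller part from such differences stays open, and no other biological explanation was tested.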
